A study of Homo sapiens with 6 samples.

How the data were processed

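RNA from ST486, an established Burkitt lymphoma cell line (a B cell cancer driven by MYC), was measured on two-colour Agilent microarrays at day 8 after lentiviral infection. The labels put 2 samples in each of 3 groups: shControl (a non-targeting short hairpin RNA, labelled Myc high), shMyc1 and shMyc2 (different short hairpin RNAs against MYC, both labelled Myc low). The 6 samples lie on 3 arrays of 1 slide from 1 scan, and each array holds the 2 samples of 1 group. Array and group can therefore not be told apart. Nothing in the labels says that the samples of a group came from separate cultures, so p-values of single features measure the spread between these samples, which may be technical. The number of arrays limits the precision.

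Per the labels, total RNA was labelled with Cy3 (green) or Cy5 (red). Per the file headers, the deposited spot intensity of each channel came from Agilent Feature Extraction 12.0.1.1 with the protocol GE2_1200_Jun14 on array design 039731, whose grid names the genome build hg19. Per the file headers, the processed signals were background-subtracted and dye-normalised within each array, and the software replaces dim spots with small positive values. The deposited series matrix holds log2 values. Its 6 columns share 1 distribution (sorted columns differ by at most 0.0087, median 3.89 in each) and are not centred per probe, so the authors' values look quantile normalised. How these log2 values were made is not given in the sources used here.

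The dye labels of shControl replicate 2 and shMyc2 replicate 1 contradict a layout of 1 sample per channel. A check fixed before the data were examined correlated each deposited log2 column with log2 of each scanner channel. The best channel lay on the array named for that sample in 6 of 6 cases (lowest best r = 0.9996, highest second r = 0.9898, across probes, which are not independent replicates), and replicate 1 was green and replicate 2 red on each array. Scanner channels were therefore used for the results, with the group taken from the array named in each sample's description.

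Each array has 62976 spots, of which 1319 are controls, and 58642 different probes that are not controls. Between 38.1% and 42.7% of these probes were well above background per channel, by the flag of the deposited files, and 0 spots were saturated. Of the probes, 28533 are custom probes whose targets are not given in the sources used here. The files give 8323 probes an accession. Without its version, the accession named a gene in a RefSeq table of assembly GRCh38.p14 for 8125 of them, which gave 7400 genes, 0 probes with several symbols, and 35 probes of non-coding RNAs. The table was used for names only and no coordinates are printed. The other 21984 catalogue probes stayed unnamed. Custom probes are not called long non-coding RNAs (lncRNAs) here, although the array was meant to hold such RNAs.

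Control spots and spots flagged as outliers (0 to 47 per channel) were left out. Processed signals were taken to log2, normalised within arrays by loess and between arrays by Aquantile, and averaged over the spots of a probe. A gene with several probes (662 named genes) was represented by the probe with the highest mean signal. A feature was tested when it was well above background in both channels of at least 1 array. This left 23764 features: 4567 named genes (4548 mRNA genes and 19 non-coding genes), 12140 unnamed catalogue probes and 7057 custom probes. A group in which a probe was not well above background in any channel has only a bound. There the change is given as "at least N-fold", against the lowest signal of probes well above background in that group, or the dim probe's own signal where higher. Each group holds 1 green and 1 red channel, so a probe's dye effect cancels between measured group means. In a bound a channel's lowest signal replaces the probe's own, so bounds remain open to some dye bias.

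Tests used limma 3.58.1 in R 4.3.3 with Benjamini-Hochberg adjustment at 0.05, and a second count required at least 2-fold. The comparison of the 4 Myc-low samples with the 2 Myc-high samples had the array as a random block (estimated correlation -0.0983, 4 residual degrees of freedom and 3.2 from the prior). Each shRNA was compared with shControl, and shMyc2 with shMyc1, in 1 model of group means (3 residual degrees of freedom and 3.4 from the prior). Gene lists (31, fixed before the data were examined) were tested with camera at a preset correlation of 0.01, with the estimated correlation and fry beside it. At the preset value camera takes the members of a list as nearly independent, so its p-values mainly measure spread across genes. Estimated correlations ran from -0.13 (MYC network partners) to 0.72 (G2 and mitosis). They were 0.67 for MYC-activated genes, 0.5 for DNA replication and 0.7 for interferon response, but 0.016 for lysosome and autophagy. Camera asks whether a list moves relative to the other named genes, while fry asks whether its members move, on balance, one way. For the pooled comparison both used the model of group means, without the array block. There the difference between shMyc1 and shMyc2 does not enter the spread, unlike in the pooled counts of genes. An official symbol on a list was never matched to another gene through that gene's older names. Lists share members. Most measured MYC-activated genes are also on the ribosome biogenesis, translation, nucleotide, glycolysis, mitochondrial or replication list. Results of these lists are therefore not independent of each other.

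Fixed before the data were examined was also the rule for naming genes. It took MYC, then the 8 mRNA genes with the largest rise, the 8 with the largest fall and up to 5 non-coding genes each way among those past the threshold in the pooled comparison and separated in all channels. It added up to 4 members of each list with the smallest p, and up to 5 genes each way for shMyc2 against shMyc1. Any gene outside this rule is marked where it is named.

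Replicate numbers coincide with the dyes. The deviations of replicates from their group means correlated at 0.291, 0.322 and 0.375 between the 3 pairs of arrays, so the numbers, or the dyes, pair the samples. A fit with a dye term equals this pairing. It is given beside most results whose call it changes or whose total count it moves by more than 1.5 times. Its split of counts into rises and falls is mostly left out.

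The fits were tested on simulated data with 200 changed features among 23764. The pooled comparison recovered 94% of changes of 1 on the log2 scale and 100% of changes of 2. The comparison of shMyc1 with shControl recovered 45% and 98%, that of shMyc2 with shControl 46% and 99%, and that of shMyc2 with shMyc1 41% and 97%. The pooled fit was too liberal: with 3 arrays the array correlation was estimated too low, and 10.2% to 10.8% of unchanged features had p under 0.05 in every simulated setting. Of its calls, 18.7% to 28.6% were then false, and it recovered 115 to 193 of the 200 changed features. Without the array block, 4.94% of unchanged features had p under 0.05 where arrays did not differ and 15.3% where arrays varied as much as channels. For shMyc1 against shControl these shares were 5.09% and 22.4%. Of the calls without the array block 2.13% to 54.5% were false, and of those for shMyc1 against shControl 0% to 85.5%, the highest where arrays varied as much as channels. With the dye term, 4.6% to 22.6% of unchanged features had p under 0.05 for shMyc1 against shControl. Of those calls 2.38% to 85.6% were false. The pooled fit with the dye term had 8.04% to 8.57% and 12.4% to 21%. Its array correlation was 0.219 in the data. In simulations it was -0.25 where arrays did not differ, and 0.29 or 0.31 where they varied as much as channels. Shares of false calls depend on how many features change, here 200, so they do not carry over to the counts in the data. The other comparisons in that model were not simulated in this way. An array effect of that kind cannot be measured with 1 array per group.

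Alternatives were other normalisations (quantile, 75th percentile shift, the deposited log2 matrix), filters on dim probes, probe summaries, the dye term, the replicate block, no array block, array means, only the 2 groups compared, leaving out each sample, other settings of limma and of the list tests, a stricter threshold and a class of RNA by accession alone. Leaving out the whole shMyc1 or shMyc2 array was added after seeing the data. Normexp correction of the raw mean signals was not run. Comparisons against the same controls were set beside 20 simulations of unchanged groups. The controls were not split, since a split of the 2 samples leaves 1 for each shRNA.

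A few single genes that were tested are not reported here, and the gene lists and counts include them.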

Results

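The effect of knocking down MYC, a transcription factor of growth and proliferation genes, on mRNAs and lncRNAs was examined in ST486 Burkitt lymphoma cells. The data held 2 samples of each of 3 groups at day 8 after infection: shControl, shMyc1 and shMyc2. Per channel, 22339 to 25055 probes were well above background. Normalised values of the 2 samples of a group correlated at 0.988 to 0.990 across features, and values of different groups at 0.953 to 0.988. Features are not independent replicates. The median absolute difference between the 2 channels of an array was 0.192 to 0.237 on the log2 scale. All levels below are normalised log2 intensities, and adjusted p-values come from limma, or from camera for gene lists, with Benjamini-Hochberg adjustment. Rises and falls are therefore relative to the total signal of an array.

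The first question was whether MYC itself was lower. It was not, in either group labelled Myc low. The MYC level was 12.88 ± 0.20 (SD, n = 2) in shControl, 13.33 ± 0.52 (n = 2) in the samples labelled shMyc1 and 13.01 ± 0.29 (n = 2) in those labelled shMyc2. The pooled difference, Myc low minus Myc high, was 0.28 (SE 0.24, adjusted p = 0.417). It was 0.44 (SE 0.28, adjusted p = 0.372) for shMyc1 and 0.12 (SE 0.28, adjusted p = 0.78) for shMyc2. Within the green channels MYC was 13.03 in shControl, 13.69 in shMyc1 and 13.21 in shMyc2. Within the red channels it was 12.74, 12.96 and 12.8. The SDs above therefore include the difference between the dyes. With a shift to the 75th percentile as the scaling, the pooled value was -0.05 (adjusted p = 0.912) and that of shMyc2 was -0.26 (adjusted p = 0.543). The array holds 1 MYC probe with a named target, which was well above background and not saturated in all 6 channels. The Myc-low and Myc-high classes below are therefore those of the labels, which MYC mRNA did not separate.

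**Figure D1:**
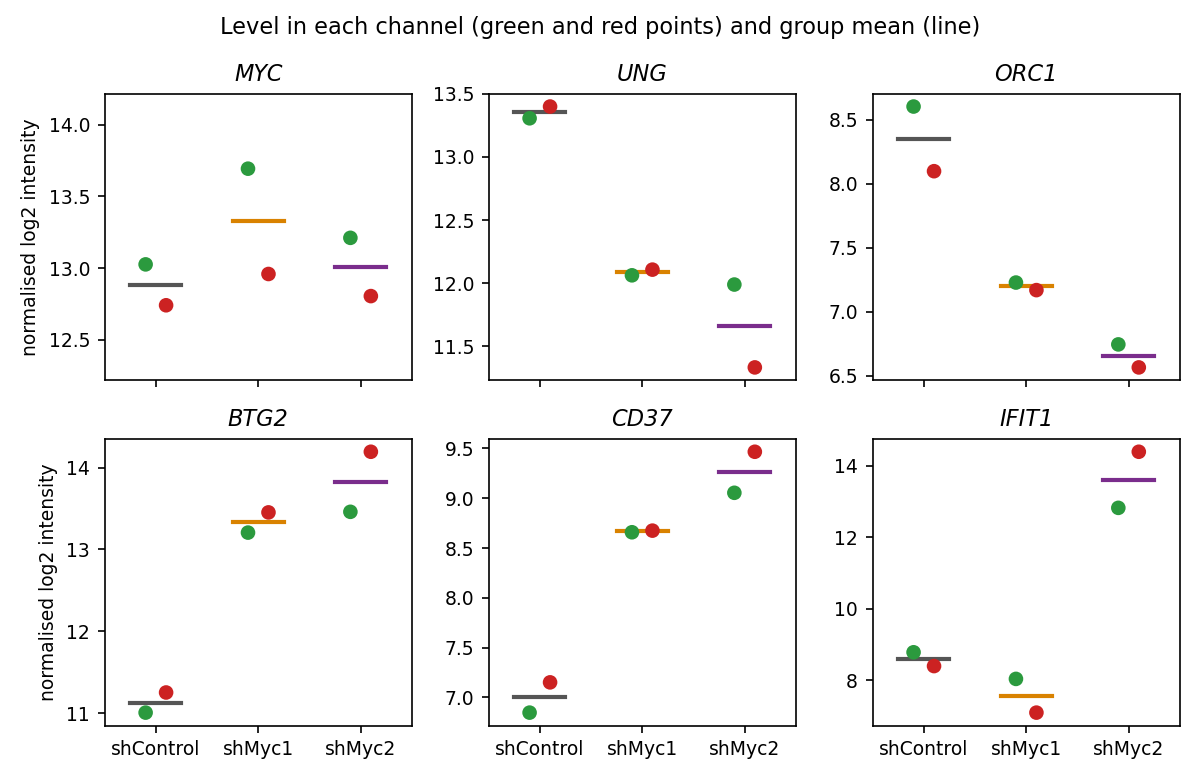
Normalised log2 intensity (y axis) of MYC, UNG, ORC1, BTG2, CD37 and IFIT1 in shControl, shMyc1 and shMyc2 (x axis), with 1 green and 1 red point per array for the channels and a line at the group mean; each panel has its own scale. MYC ranged from 12.74 to 13.69. Its groups overlapped across the dyes, while within each dye it was lowest in shControl and highest in shMyc1. UNG and ORC1 were lower in all 4 Myc-low channels, BTG2 and CD37 were higher in them, and IFIT1 was high in both shMyc2 channels only among the 6.

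In the samples labelled Myc low as a whole, compared with shControl, gene lists of growth, nucleotide synthesis and DNA replication were lower, and those of lysosomes and the B cell surface were higher, with camera's preset correlation but not with an estimated one (0 of 31 lists, lowest adjusted p = 0.35). Interferon genes were higher mainly in shMyc2 (23 of 23 past the threshold, against 0 of 23 in shMyc1). Of 23764 features, 3789 changed (2123 up, 1666 down), of which 1136 changed at least 2-fold. With the dye term 1003 changed (616 at least 2-fold). Of these 1003, 978 were among the 3789, and without the array block 2476 changed, all among the 3789. The 75th percentile shift gave 1836 up and 2679 down, which is 40.7% up against 56%. On simulated data 18.7% to 28.6% of the calls of this fit were false, and with array means as the samples 0 features passed in limma (5016 at an unadjusted p under 0.05). The count was 45 without shControl replicate 1, 25 without shControl replicate 2, 11302 and 11831 without shMyc1 replicates 1 and 2, and 8704 without shMyc2 replicate 2.

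Among mRNA genes the largest fitted rises were those of HBB, CKM, TF, CCR1, NUAK2, BTG2, LTB and NPPA. Fitted changes, which set the ranking, include dim channels at their small values. The rank of genes given below as bounds is therefore uncertain. BTG2, an antiproliferative gene, rose by 2.45 (SE 0.26, adjusted p = 0.009), a 5.46-fold change, and LTB, the lymphotoxin beta gene, rose 5.33-fold (adjusted p = 0.0116). The kinase gene NUAK2 rose 6.6-fold (adjusted p = 0.00959), with 1 of 2 control channels well above background. HBB, a haemoglobin gene, was not well above background in shControl and was at least 6.97-fold higher (adjusted p = 0.0127). The chemokine receptor gene CCR1 was at least 3.54-fold higher (adjusted p = 0.0303, 0.0607 with the dye term) and the muscle creatine kinase gene CKM, measured in 3 of 4 Myc-low channels, at least 2.84-fold (0.0256, 0.0609 with the dye term). TF, which encodes transferrin, was at least 1.82-fold higher (adjusted p = 0.00211) and the natriuretic peptide gene NPPA (0.0278, 0.0614 with the dye term), well above background in shMyc2 only, was at least 2.67-fold higher there (0.0167). The largest fitted falls were those of CD247, ID1, ANK3, ABCC4, HEBP1, AKR1C3, MYCL and SRGN. ID1, an inhibitor of differentiation, fell by 2.45 (SE 0.36, adjusted p = 0.0135). HEBP1 (adjusted p = 0.00912) was not well above background in shMyc1 and was at least 4.12-fold lower there (0.0406). SRGN (adjusted p = 0.0135) was not well above background in shMyc2 and was at least 4.37-fold lower there (0.0135). CD247, a T cell receptor signalling gene, was not well above background in the Myc-low channels and was at least 2.74-fold lower (adjusted p = 0.00875). The MYC relative MYCL was at least 2.5-fold lower (adjusted p = 0.0366, 0.0567 with the dye term), AKR1C3 at least 2.09-fold (0.0177), ANK3 at least 1.88-fold (0.0146) and ABCC4 at least 1.73-fold (0.0177, 0.0589 with the dye term).

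**Figure D2:**
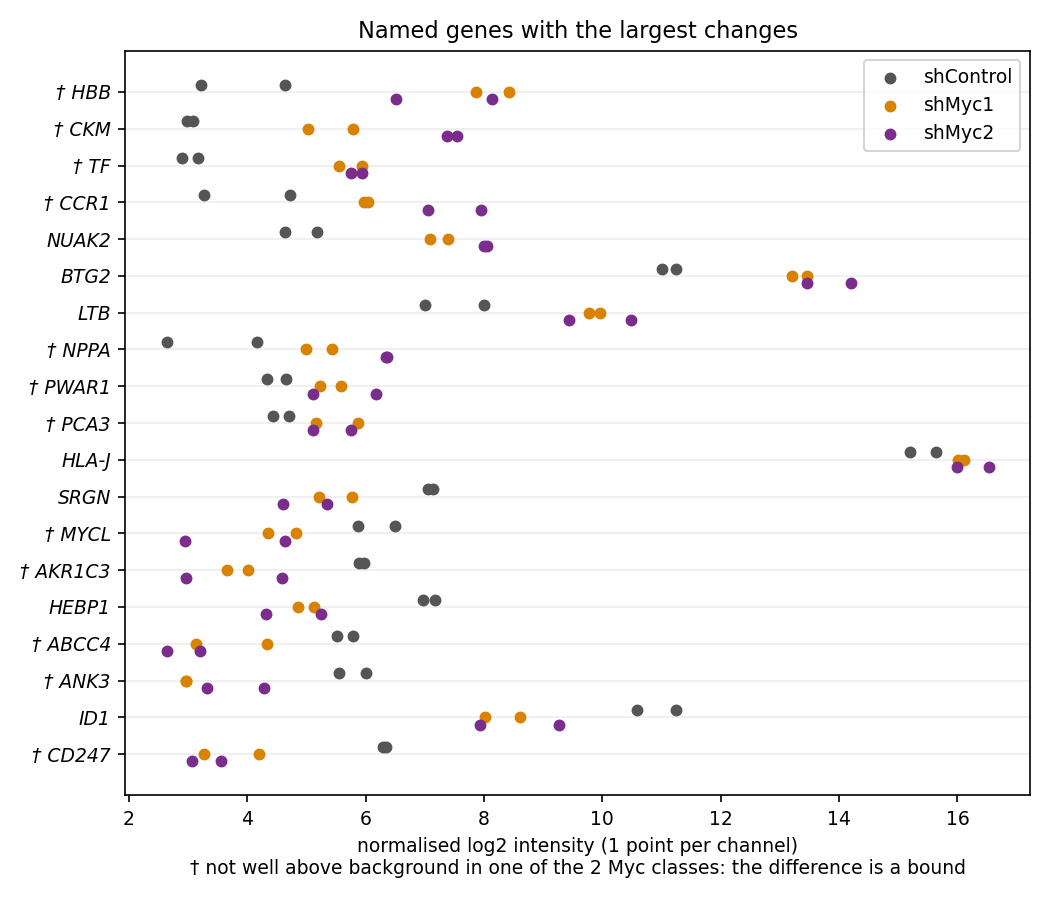
Normalised log2 intensity (x axis, 1 point per channel, n = 2 per group) of the named genes with the largest fitted pooled changes (y axis), coloured by group. The rule of choice took only genes whose shControl points lie apart from the Myc-low points, and BTG2 had means of 11.13 in shControl, 13.33 in shMyc1 and 13.83 in shMyc2. A dagger marks genes not well above background in one Myc class, for which the report gives a bound.

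Targets that MYC is known to activate were lower. Of 22 measured genes of that list, 15 fell and 0 rose (9 fell with the dye term, 21 adjusted over the list alone), with a median log2 change of -0.795 (camera adjusted p = 9.03e-09, but adjusted p = 0.35 with an estimated correlation). UNG, a DNA repair glycosylase, fell by 1.48 (SE 0.22, adjusted p = 0.0137), PA2G4 by 0.90 (0.0134), PHB1 by 0.90 (0.0163) and SRM, spermidine synthase, by 0.85 (0.0153). In nucleotide and polyamine synthesis, 13 of 26 fell (3 with the dye term, 17 adjusted over the list alone; median -0.654, camera adjusted p = 1.13e-06), among them SRM, NME1 (-0.69, adjusted p = 0.0181) and ODC1 (-0.80, 0.0219). In ribosome biogenesis, 8 of 18 fell (3 with the dye term, 10 over the list alone; median -0.499, camera adjusted p = 6.84e-05), including NOLC1 (-0.92, adjusted p = 0.02) and TCOF1 (-0.81, 0.0181). Translation factors and tRNA synthetases had 4 of 28 that fell past the threshold (0 with the dye term, 8 over the list alone; median -0.26, camera adjusted p = 0.00605). Cytoplasmic ribosomal proteins moved little: 1 of 24 fell (0 with the dye term, 0 over the list alone; median -0.215, camera adjusted p = 0.037, but 0.0728, 0.0819 and 0.147 under 3 other scalings). The 1 gene was RPS21 (-0.47, adjusted p = 0.0474, 0.097 with the dye term, and 0.0522 and 0.0555 under 2 other scalings). With an estimated correlation, the adjusted p was 0.35 for nucleotide synthesis, 0.42 for ribosome biogenesis, 0.56 for translation factors and 0.62 for ribosomal proteins.

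With camera's preset correlation, 3 further lists were lower: glycolysis, glutamine and serine-glycine metabolism, mitochondrial biogenesis and import, and chaperones. The glycolysis and mitochondrial lists share members with the MYC-activated list, PHB1 and HSPE1 among them for the mitochondrial list. Of the list of glycolysis, glutamine and serine-glycine metabolism, 8 of 27 fell (3 with the dye term, 9 over the list alone; median -0.402, camera adjusted p = 4.62e-05). SLC16A1, a lactate transporter, fell by 1.07 (SE 0.15, adjusted p = 0.0126), the folate enzyme gene MTHFD1L by 0.998 (0.0195) and PGAM1 by 0.82 (0.0171). In mitochondrial biogenesis and import, 9 of 21 fell and 1, POLG2, rose (4 and 0 with the dye term, 14 and 1 over the list alone; median -0.488, camera adjusted p = 0.000325). TRAP1 fell by 0.89 (adjusted p = 0.0159) and HSPE1 by 0.79 (0.0177), while POLG2 rose by 0.70 (0.0211, 0.054 with the dye term). Of the chaperones, 6 of 18 fell (1 with the dye term, 8 over the list alone; median -0.487, camera adjusted p = 0.000557), including FKBP4 (-0.76, adjusted p = 0.0145). These 3 lists had adjusted p = 0.35 with an estimated correlation. Of 20 oxidative phosphorylation genes, 0 passed the threshold in limma (2 at an unadjusted p under 0.05; 0 adjusted over the list alone; median -0.116, camera adjusted p = 0.217, but 0.0231 with the 75th percentile shift). In cholesterol and fatty acid synthesis, 6 of 20 fell and 1 rose (3 and 0 with the dye term, 9 and 3 over the list alone), among them FASN (-1.06, adjusted p = 0.0185), ACACA (-0.86, 0.0216) and DHCR7 (-0.74, 0.0174), while MVD, chosen after its values were seen, rose (0.59, 0.044, 0.103 with the dye term). The list as a whole did not pass (median -0.232, camera adjusted p = 0.071, but 0.0296 with the 75th percentile shift).

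DNA replication genes were among the lowest. Of 33 genes of DNA replication and S phase, 12 fell and 0 rose (2 with the dye term, 27 over the list alone), with a median of -0.785 (camera adjusted p = 5.59e-12, adjusted p = 0.35 with an estimated correlation). ORC1, a subunit of the origin recognition complex, fell by 1.42 (SE 0.24, adjusted p = 0.0173), POLE2 by 1.38 (0.0249, 0.0703 with the dye term) and the helicase gene MCM6 by 1.18 (0.0264, 0.0668 with the dye term). Of 29 genes of G2 and mitosis, 1, AURKA, fell (0 with the dye term, 0 over the list alone; median -0.531, camera adjusted p = 1.13e-06, adjusted p = 0.45 with an estimated correlation). AURKA fell by 0.80 (adjusted p = 0.0375, 0.0797 with the dye term). Among CDK inhibitors, cyclin D and growth arrest genes, 5 of 15 rose (1 with the dye term, 5 over the list alone; median 0.257, camera adjusted p = 0.0154, adjusted p = 0.35 with an estimated correlation). These included BTG2, CCNG2 (0.89, adjusted p = 0.0375, 0.0592 with the dye term) and CDKN1B (0.66, 0.0344, 0.0516 with the dye term and 0.055 with the 75th percentile shift), which encodes the cell cycle inhibitor p27. The list of growth arrest genes passed in shMyc1 alone (camera adjusted p = 0.00175) but not in shMyc2 alone (0.0828).

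Lists of B cell receptor and surface genes, plasma cell and activated B cell genes, and antigen presentation were higher with camera's preset correlation. Of the B cell receptor and surface genes, 8 of 19 rose (4 with the dye term, 10 over the list alone; median 0.545, camera adjusted p = 3.33e-05). CD37 rose by 1.96 (SE 0.25, adjusted p = 0.011) and the receptor subunit gene CD79B by 1.18 (0.0181). Of the plasma cell and activated B cell genes, 5 of 22 rose (5 with the dye term, 8 over the list alone; median 0.528, camera adjusted p = 0.00115). TRAF1 (1.34, adjusted p = 0.011), CD80 (1.22, 0.011), RELB (1.06, 0.0126) and NFKB2 (0.85, 0.0171) were the leading members, with TRAF1 well above background in 1 of 2 control channels. In antigen presentation, 4 of 22 rose (0 with the dye term, 11 over the list alone; median 0.419, camera adjusted p = 3.33e-05), including TAPBP (0.92, adjusted p = 0.0216, 0.0621 with the dye term) and the protease gene CTSS (0.85, 0.0414, 0.0685 with the dye term). These 3 lists had adjusted p = 0.35 with an estimated correlation. Of the germinal centre genes, 4 of 19 rose (1 with the dye term, 4 over the list alone), and the list did not pass (median 0.351, camera adjusted p = 0.0526, 0.016 with the dye term). NEIL1, a DNA glycosylase, rose by 2.05 (SE 0.23, adjusted p = 0.00922) and S1PR2 by 1.97 (0.0417, 0.0748 with the dye term).

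Of the lysosome and autophagy genes, 16 of 28 rose past the threshold and 0 fell (5 with the dye term, 20 over the list alone; median 0.614, 0.591 with dim groups at their bound, camera adjusted p = 1.04e-07, adjusted p = 0.35 with an estimated correlation). TFEB, a transcription factor of lysosomal genes, rose by 1.002 (SE 0.14, adjusted p = 0.0122), the protease gene TPP1 by 0.97 (0.0122) and the autophagy gene MAP1LC3B by 0.95 (0.0126). In the BCL2 family and apoptosis list, 4 of 20 rose and 1 fell (1 and 0 with the dye term, 6 and 2 over the list alone; median 0.302, camera adjusted p = 0.0235, adjusted p = 0.35 with an estimated correlation). BMF, with 1 of 2 control channels well above background, rose 3.57-fold (adjusted p = 0.0199, 0.0517 with the dye term), BIK 1.67-fold (0.0206), and BNIP3, which is induced by hypoxia, was 2.53-fold lower (0.0229, 0.0507 with the dye term). Of the p53 targets, 2 of 17 rose (2 with the dye term, 2 over the list alone), TP53INP1 by 1.98 (SE 0.18, adjusted p = 0.00694) and ZMAT3 by 1.24 (0.0162; list median 0.252, camera adjusted p = 0.024, adjusted p = 0.45 with an estimated correlation). In shMyc1 alone neither the BCL2 family list (camera adjusted p = 0.111) nor the p53 list (0.0824) passed. In shMyc2 alone both did (0.0106 and 0.0144). Of 23 interferon response genes, 4 rose (1 with the dye term, 4 over the list alone; median 1.94, 1.76 with dim groups at their bound, camera adjusted p = 5.65e-12, adjusted p = 0.35 with an estimated correlation). These were MX1 (1.94, adjusted p = 0.0117), STAT2 (1.504, 0.0248, 0.0619 with the dye term), IRF1 (0.93, 0.041, 0.0792 with the dye term) and IRF9 (2.17, 0.0472, 0.0863 with the dye term). The list median was 3.11 in shMyc2 and 0.397 in shMyc1. This gap counts as spread in the pooled limma fit but not in the camera test.

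The remaining lists did not pass with camera except 1. Of 7 MYC network partners, MXD1 rose (0.50, adjusted p = 0.037, 0.078 with the dye term) and MYCL and MXI1 (-0.66, 0.0375, 0.0728 with the dye term) fell (1 up and 2 down over the list alone; median 0.13, mean -0.20, camera direction up, adjusted p = 0.636). Its median was -0.163 with the 75th percentile shift. In the integrated stress and unfolded protein response, 2 of 16 rose (0 with the dye term, 2 over the list alone), namely HERPUD1 (0.59, adjusted p = 0.0279, 0.0708 with the dye term and 0.139 with the 75th percentile shift) and PPP1R15A (1.02, 0.0296, 0.0846 with the dye term), with a median of 0.00405 (adjusted p = 0.872) that was -0.218 with that shift. Of 4 replication-dependent histone genes 0 passed in limma, also over the list alone (1 at an unadjusted p under 0.05; median 0.0203, adjusted p = 0.597, median -0.147 with that shift). Of 15 housekeeping genes 2 fell, among them TFRC (-0.79, adjusted p = 0.0289, 0.0707 with the dye term). Over the list alone 1 rose and 3 fell (median -0.159, camera adjusted p = 0.393).

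Markers of other cell types were included as a background. Most did not pass the filter. Measured were 4 of 13 myeloid markers on the array, 6 of 13 for T and NK cells, 4 of 12 fibroblast, endothelial and erythroid, and 2 of 13 epithelial and producer. CD68 and HBB were not well above background in shControl, so they entered only through Myc-low arrays. The lists therefore favour markers that are high in some group. Of 4 measured myeloid markers, ITGAM rose by 1.44 (SE 0.19, adjusted p = 0.0111), CD14 by 0.74 (0.0455, 0.107 with the dye term) and CD68 was at least 2.77-fold higher (0.0302, 0.062 with the dye term). This list passed (3 up over the list alone; median 1.09, camera adjusted p = 0.00741, adjusted p = 0.35 with an estimated correlation), with levels of ITGAM of 5.38 in shControl, 6.65 in shMyc1 and 6.99 in shMyc2. Of 6 T cell and NK markers, CD3D fell by 0.74 (adjusted p = 0.0202, 0.0558 with the dye term; 3 down over the list alone, median -0.483, camera adjusted p = 0.0554). Of 4 fibroblast, endothelial and erythroid markers, HBB and the endothelial PECAM1 (1.73, adjusted p = 0.029, 0.0683 with the dye term) rose (2 over the list alone; median 0.894, camera adjusted p = 0.155). Of the 2 epithelial and producer cell markers measured, VIM had a change of -0.70 (adjusted p = 0.0553, 0.0276 and 0.0476 under 2 other scalings) and KRT8 of 0.24 (0.241; 0 passed over all features, 1 over the list alone, median -0.231, camera adjusted p = 0.681).

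Some of the pooled calls above depend on the fit or the filter. Without the array block those of MYCL (adjusted p = 0.0507), MXD1, MXI1, RPS21, CCNG2, S1PR2, CTSS, IRF1, IRF9 and CD14 ended (0.0504 to 0.0653). Without the filter on dim probes those of MYCL (0.0857), CKM, CCR1, NPPA, MXI1, POLE2, MCM6, AURKA, CCNG2, BMF, BNIP3, S1PR2, CTSS, STAT2, IRF1, IRF9, PPP1R15A, CD68, CD14, PECAM1 and TFRC ended (0.0513 to 0.115). With the mean of a gene's probes those of MXI1 (0.0565) and PGAM1 (0.0519) did.

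The second question concerned mRNAs against non-coding RNAs. The Wilson intervals below treat features as independent and hold no spread between samples or arrays. They therefore do not test a difference between classes of RNA. Of 4548 mRNA genes, 805 changed, which is 17.7% (95% Wilson interval 16.6 to 18.8), and 237 changed with the dye term. Their count was 4 and 2 without shControl replicates 1 and 2, 2193 and 2396 without shMyc1 replicates 1 and 2, 1700 without shMyc2 replicate 2, and 0 with array means. Of 19 non-coding genes with a name, 3 changed, which is 15.8% (5.52 to 37.6), and 0 with the dye term, where 5 had an unadjusted p under 0.05 in limma. The 3 genes were PWAR1, at least 1.51-fold higher (adjusted p = 0.0474), PCA3, at least 1.46-fold higher (0.0433), and HLA-J, a pseudogene transcript, which rose by 0.74 (0.0437). With the dye term their adjusted p was 0.115, 0.129 and 0.062, that of HLA-J was 0.0631 with the 75th percentile shift, and without the array block 0 of them passed (6 at an unadjusted p under 0.05). Without the filter on dim probes all 3 calls ended too (0.0904, 0.0796 and 0.0731), and with trend and robust settings of limma those of PWAR1 and PCA3 (0.0565 and 0.062). HLA-J shares sequence with other HLA genes, so its probe is uncertain. Of 5 measured genes on the lncRNA list, 0 passed in limma, also over the list alone (2 at an unadjusted p under 0.05; median 0.219, camera adjusted p = 0.681): KCNQ1OT1 had a change of 1.12 (SE 0.42, adjusted p = 0.103), and TERC of -0.38 (0.118, 0.0471 with the 75th percentile shift). RMRP, the RNA of a ribonuclease, had a change of 0.38 (adjusted p = 0.267). It was also the only measured entry on the list of small nucleolar RNA host genes, of which it is none, so that list tells nothing about host genes. Of 7057 custom probes with targets not given here, 1094 changed, which is 15.5% (14.7 to 16.4), 727 up and 367 down, and 269 changed with the dye term. Their count was 17 and 10 without shControl replicates 1 and 2, 3288 and 3319 without shMyc1 replicates 1 and 2, 2572 without shMyc2 replicate 2, and 0 with array means (1626 at an unadjusted p under 0.05). CUST_8977_PI427622068, with 1 of 2 control channels well above background, rose by 3.52 (SE 0.41, adjusted p = 0.01), and CUST_37832_PI427622066 was at least 3.58-fold lower (adjusted p = 0.00694).

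Next, each shRNA was compared with shControl on its own. In the samples labelled shMyc1, lists of growth and replication genes were lower and those of B cell and lysosome genes higher with camera's preset correlation. With an estimated correlation 0 of 31 lists passed (lowest adjusted p = 0.31), and fry called 5 up and 0 down (adjusted p = 0.052 for MYC-activated genes and 0.07 for DNA replication). Of 23764 features 467 changed (297 up, 170 down, 405 at least 2-fold), and 2215 changed with the dye term (900 at least 2-fold). The split was 328 up and 300 down with the 75th percentile shift, and 59 up and 70 down without the filter on dim probes. On simulated data with 200 changed features, 0% to 85.5% of the calls of this fit were false, most where arrays varied as much as channels. With the dye term 2.38% to 85.6% were false. Those shares do not carry over to the 467 or the 2215. TP53INP1 rose by 2.00 (SE 0.24, adjusted p = 0.0338), BTG2 by 2.20 (0.0338), NEIL1 by 1.79 (0.0321), CD37 by 1.67 (0.0338) and CD72 by 1.41 (0.0317). PHB1 fell by 1.03 (0.0425), SLC16A1 by 0.93 (0.048), and ANK3 was at least 1.72-fold lower (0.0325). HBB was at least 9.25-fold higher (adjusted p = 0.0425). The MYC-activated list had a median of -0.692 (1 of 22 fell, 12 with the dye term, 18 over the list alone, camera adjusted p = 2.6e-09), DNA replication and S phase of -0.535 (0 of 33 fell, 20 at an unadjusted p under 0.05, 4 with the dye term, 9 over the list alone, 3.45e-08) and lysosome and autophagy of 0.539 (2 of 28 rose, 9 with the dye term, 16 over the list alone, 9.03e-08). B cell receptor and surface genes had a median of 0.488 (2 of 19 rose, 7 with the dye term, 9 over the list alone, 3.64e-06) and interferon response genes of 0.397 (0 of 23 rose, 9 at an unadjusted p under 0.05, 4 with the dye term, 3 over the list alone, 0.00949). G2 and mitosis did not pass (median -0.211, 0 of 29 in limma, 2 at an unadjusted p under 0.05, camera adjusted p = 0.0629). In all, 16 of 31 lists passed with camera's preset correlation (8 up, 8 down). With only the 2 groups compared in the fit 202 features changed. The count was 0 and 24 without shControl replicates 1 and 2 (4232 and 4315 at an unadjusted p under 0.05), 2 and 6 without shMyc1 replicates 1 and 2, and 202 without either shMyc2 replicate.

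In the samples labelled shMyc2, the same lists moved further for replication and interferon genes. Of 23764 features 3997 changed (2176 up, 1821 down, 1980 at least 2-fold), and 7257 with the dye term. With the 75th percentile shift 1997 rose and 2977 fell, which turns the majority, and without the filter on dim probes 683 changed (402 up, 281 down). All 23 interferon response genes rose (23 over the list alone), with a median of 3.11 (3.01 with dim groups at their bound, camera adjusted p = 6.35e-16, adjusted p = 0.37 with an estimated correlation). IFITM1 rose by 5.59 (SE 0.45, adjusted p = 0.006), IFIT1 by 5.01 (0.00906), IFI6 by 3.85 (0.0092) and IRF9 by 3.01 (0.00727). EPSTI1 was at least 17.8-fold higher (0.00419). Of 33 replication genes 31 fell (32 over the list alone, median -1.1, camera adjusted p = 2.4e-14), including ORC1 (-1.69, adjusted p = 0.0112) and UNG (-1.69, 0.0133). Of 29 genes of G2 and mitosis 21 fell (28 over the list alone, median -0.88, camera adjusted p = 7.06e-10), including CCNA2 (-1.11, adjusted p = 0.019) and AURKA (-1.03, 0.0168). Both cell cycle lists had adjusted p = 0.37 with an estimated correlation. Of the MYC-activated genes 14 of 22 fell (19 over the list alone, median -0.798, camera adjusted p = 8.18e-08), and of the lysosome genes 15 of 28 rose (18 over the list alone, median 0.73, camera adjusted p = 2.42e-07), also with adjusted p = 0.37 with an estimated correlation. CD37 rose by 2.26 (adjusted p = 0.00722) and S1PR2 by 2.66 (0.00938). In all, 17 of 31 lists passed (8 up, 9 down), and with an estimated correlation 0 did (lowest adjusted p = 0.37). With the 75th percentile shift the median of all features was -0.107 in this comparison, against -0.0219 here, so changes under that scaling are relative to that shift. With only the 2 groups compared 2465 features changed, as without either shMyc1 replicate, and the count was 191 without shMyc2 replicate 2, 416 without shControl replicate 1 and 424 without shControl replicate 2.

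**Figure D3:**
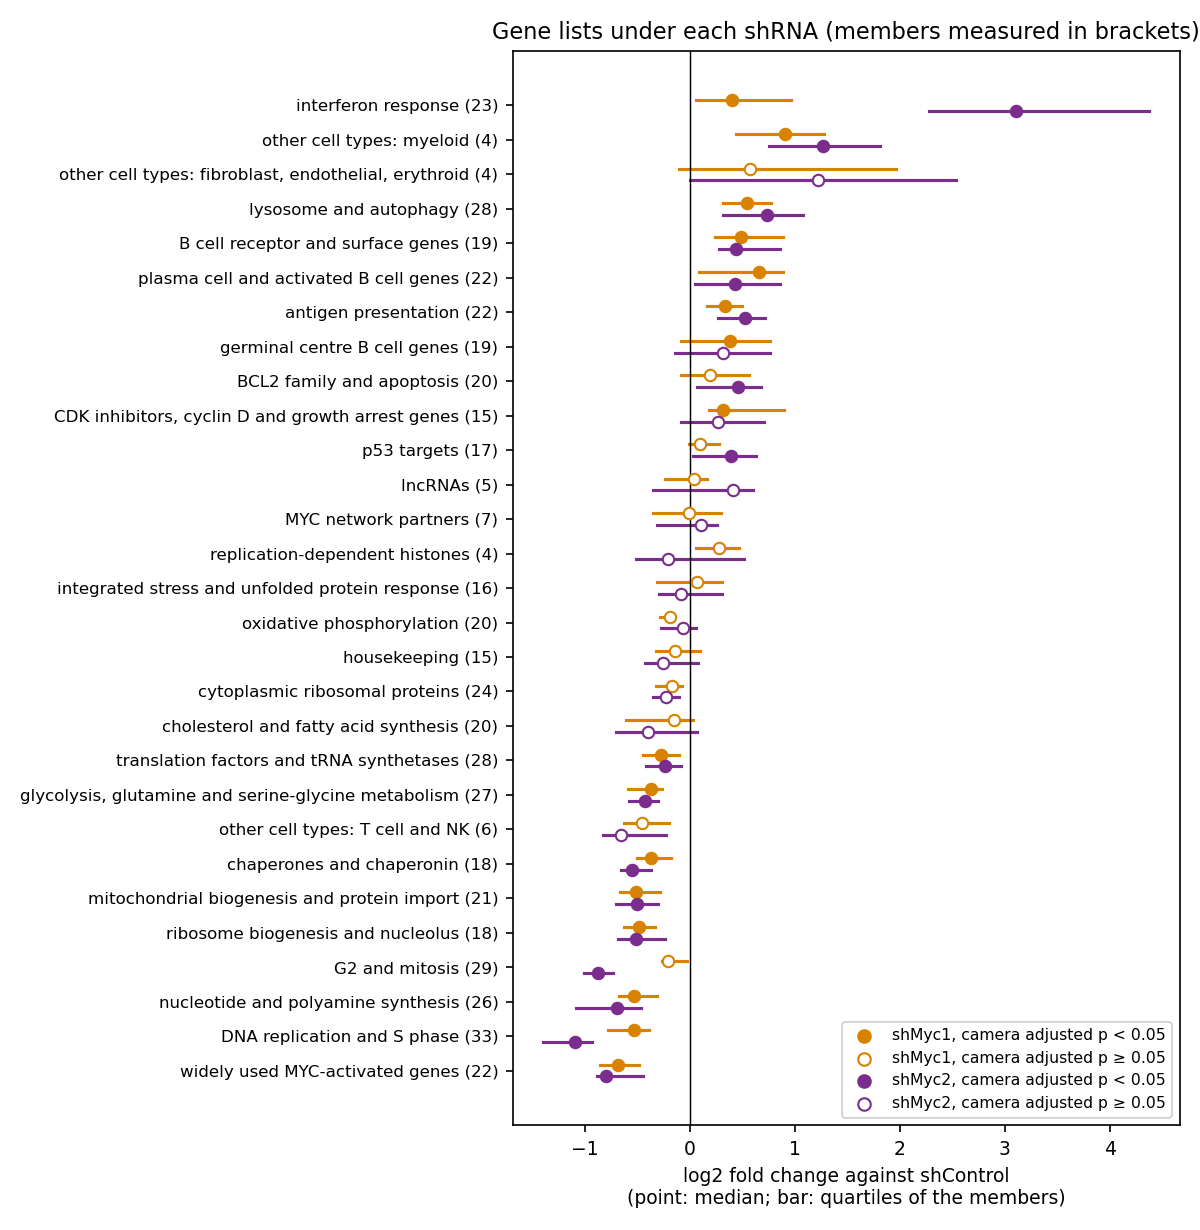
Median log2 fold change (x axis) of each gene list with at least 4 measured members (y axis, members in brackets), for shMyc1 and shMyc2 against shControl, with bars from the lower to the upper quartile of the members and filled points where camera's adjusted p was under 0.05. Most lists lie on the same side of 0 under both shRNAs, and interferon response shows the widest gap (0.397 against 3.11).

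Many features changed the same way under both shRNAs. Of 23764 features, 412 were called in both comparisons in the same direction (277 up, 135 down), 314 of them at least 2-fold in both, and 2 in opposite directions. The 412 were 88 mRNA genes (64 up, 24 down), 0 of 19 non-coding genes (upper Wilson limit 16.8%), 111 custom probes and 213 unnamed catalogue probes. The shared calls were 307 up and 250 down with the 75th percentile shift (63 and 60 for mRNA genes), and 31 up and 60 down without the filter on dim probes (8 and 8). With the dye term the shared calls were 1896, among them 441 mRNA genes, 526 custom probes and 929 unnamed catalogue probes. Of these 1896, 661 were at least 2-fold in both, and 5 further features were called in opposite directions. BTG2, NUAK2, NEIL1, TP53INP1, CD37, TRAF1, CD80 and TPP1 were called higher in both, and CD247, HEBP1, PHB1 and SLC16A1 lower. Independent lists of these sizes would share 27.2 features up and 13 down, and in simulations of unchanged groups against shared controls 0 were shared. Fold changes of the 2 comparisons correlated at 0.796 across features, where shared controls alone gave 0.50 (highest of 20 simulations 0.515). Their covariance was 0.268 against 0.0275 (highest 0.0292), and 82.9% of features had the same sign against 66.7%. With 2 control samples no split leaves 2 for each shRNA, so part of the excess may come from the shared controls. Both control samples lie on 1 array, and an effect of that array would enter both comparisons in the same direction. Such an effect cannot be measured here, so neither the independent lists nor the simulations give a baseline that covers it. The shared calls were 0 and 22 without shControl replicates 1 and 2 (3236 and 3280 at an unadjusted p under 0.05 in both), 1 and 2 without shMyc1 replicates 1 and 2, and 182 and 77 without shMyc2 replicates 1 and 2.

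**Figure D4:**
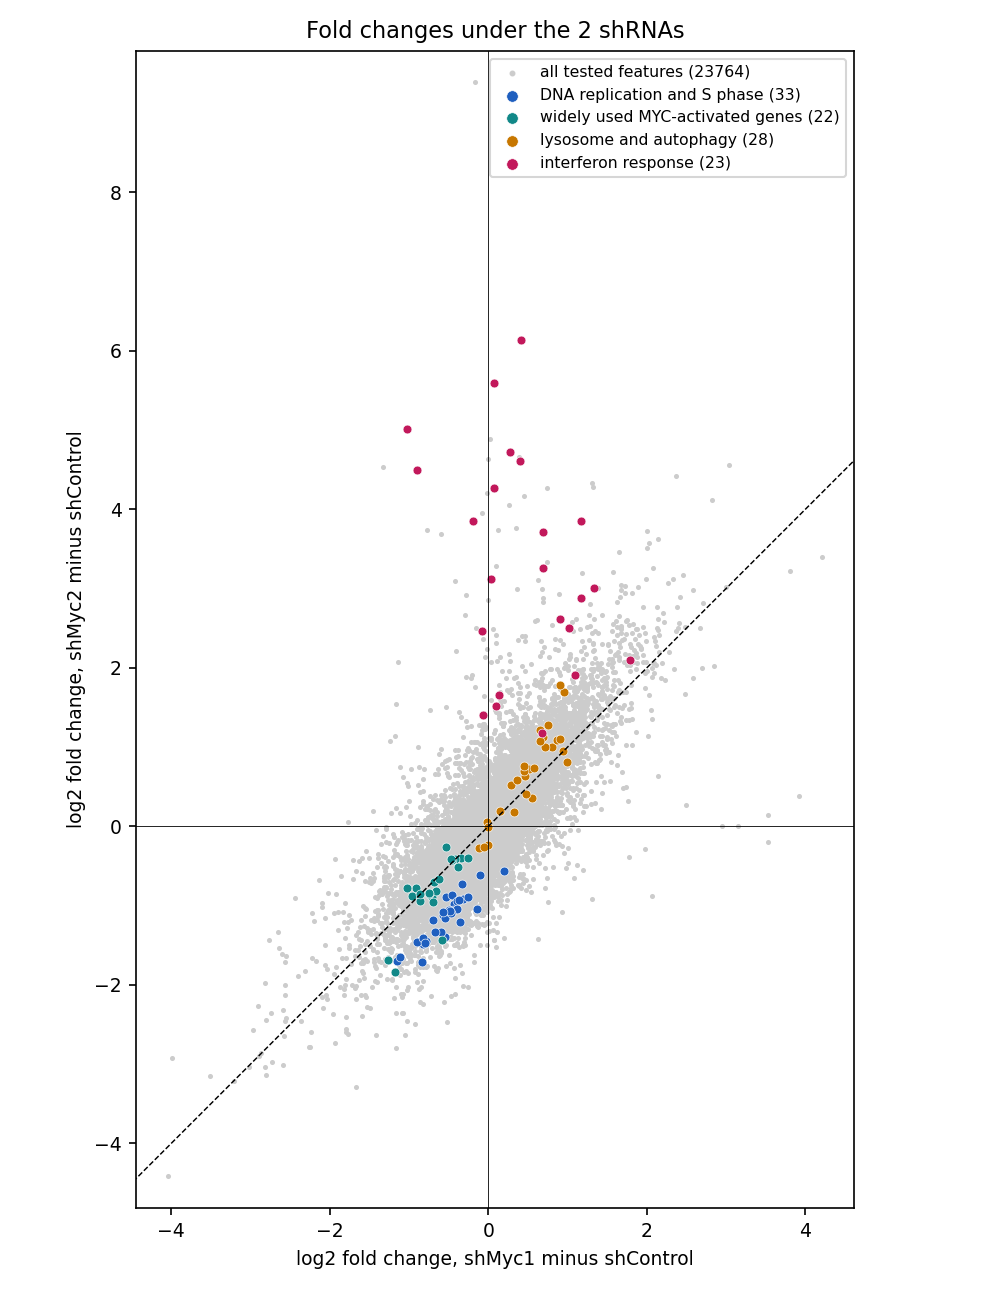
Log2 fold change of each of 23764 features in shMyc1 (x axis) and shMyc2 (y axis), both against shControl, with 4 gene lists coloured and a dashed line where both are equal. Replication genes lie below 0 for shMyc2 in all 33 cases, 24 of 28 lysosome genes lie above 0 for each shRNA, and 23 of 23 interferon genes lie above the dashed line, some close to it (MX1 by 0.30).

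The direct comparison of shMyc2 with shMyc1 found interferon genes higher in shMyc2. Of 23764 features 27 differed (25 up, 2 down, 27 at least 2-fold, 37 with the dye term). Without the filter on dim probes 28 were higher and 23 lower, and with trend and robust settings of limma 81 and 11. All 11 named genes among them were higher in shMyc2, and 6 are on the interferon list. IFIT1 was higher by 6.04 (SE 0.54, adjusted p = 0.0293, 0.0599 with the dye term), IFITM1 by 5.52 (SE 0.45, 0.0217) and IFI6 by 4.04 (SE 0.42, 0.0446). EPSTI1 was at least 17.1-fold higher (adjusted p = 0.0208) and PLAAT2 at least 6.69-fold (0.0217). Of 23 interferon genes 6 rose (7 with the dye term, 21 over the list alone), with a median difference of 2.57 (2.54 with dim groups at their bound, camera adjusted p = 3.11e-28). Replication genes were lower in shMyc2 (median -0.591, 0 of 33 over all features, 27 at an unadjusted p under 0.05, 24 over the list alone, camera adjusted p = 3.49e-17), as were genes of G2 and mitosis (median -0.675, 0 of 29 over all features, 27 both unadjusted and over the list alone, 5.44e-20). With an estimated correlation these 3 lists had adjusted p = 0.63, and fry called 0 of 31 (lowest adjusted p = 0.14). Further lists past the threshold were nucleotide and polyamine synthesis (median -0.135, adjusted p = 0.0289), lysosome and autophagy (0.191, 0.00916), antigen presentation (0.15, 0.0289, 0.0958 with the 75th percentile shift) and BCL2 family and apoptosis (0.215, 0.0487, 0.0623 with the dye term, and 0.0508, 0.0509 and 0.0547 under 3 other scalings), with 0.63 to 0.81 under an estimated correlation. MYC-activated genes showed no difference past the threshold (median -0.0717, camera adjusted p = 0.485). Each shRNA was measured on 1 array, so the hairpin and the array cannot be told apart, and with the filter at all 6 channels 15 features differed. The count was 6 without either shControl replicate, 9 and 7 without shMyc1 replicates 1 and 2 (the 7 were 3 up and 4 down), and 51 without shMyc2 replicate 1.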

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

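The tests of the scaling, and that of the shMyc2 array against its hairpin, were chosen only after the results were seen. All results here were picked out because the samples labelled shMyc2 and shMyc1 differed in a direct test of the difference, with 27 features past the threshold in limma (adjusted p under 0.05).

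The interferon response list was higher in shMyc2 by a median of 2.57 on the log2 scale, and the difference was positive for 23 of 23 genes. IFIT1 was higher by 6.04, EPSTI1 by 5.72 in the fit (at least 17.1-fold, as it was not well above background in shMyc1), IFITM1 by 5.52 and IFI6 by 4.04. PLAAT2, which is not on that list, was higher by 4.86 in the fit (at least 6.69-fold, for the same reason as EPSTI1). MX1, on the interferon list, showed a difference of 0.30 (SE 0.32, adjusted p = 0.801). Tested spots within 2 rows and columns of the interferon spots (287 spots) had a median difference of 0.118, which argues against a local artefact of the array surface. Under 3 other scalings the list median stayed between 2.48 and 2.56, so it did not depend on the choice among them. These scalings put the median of all features in this comparison between -0.0374 and 0.00113. They could hardly have removed such a difference, so scaling as a cause was not put to a real test. Each shRNA lies on 1 array, so an effect of the shMyc2 hairpin or its virus cannot be told apart from an event in that culture, labelling or array. A response to the shMyc2 construct may be a candidate explanation, as a hypothesis only.

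The DNA replication and S phase list was lower in shMyc2, with a median difference of -0.591, and so was the list of G2 and mitosis, with -0.675, in 33 of 33 and 29 of 29 genes. Within the dyes the median of both lists together was -0.439 for the one nearer 0 and -0.821 for the other, which argues against an effect of 1 dye on 1 array. An effect common to the arrays cancels by the design and was not tested. Under 3 other scalings the median of both lists lay between -0.623 and -0.697, so it did not depend on the choice among them. As these scalings moved the median of all features little, this could hardly have come out otherwise. A lower share of dividing cells with shMyc2 may be a candidate explanation, and remains open beside an event on that 1 array. MYC mRNA showed a difference of -0.32 between them (SE 0.28, adjusted p = 0.756), and the MYC-activated list one of -0.0717 (camera adjusted p = 0.485).

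Of the other lists, nucleotide and polyamine synthesis differed by a median of -0.135, lysosome and autophagy by 0.191, antigen presentation by 0.15 and BCL2 family and apoptosis by 0.215. With an estimated correlation, the adjusted p of all 7 lists lay between 0.63 and 0.81.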

How the results depend on the processing

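Leaving out the whole shMyc1 or shMyc2 array was chosen only after the results were seen. Over all alternatives, 1763 values of named genes kept their direction and side of the threshold, 593 lost the call, 104 gained it and 9 changed sign. For gene lists these numbers were 599, 66, 17 and 19. The values that kept their side include genes and lists past the threshold in neither fit. Quantile scaling, the deposited log2 matrix and the mean of a gene's probes changed no count of features, mRNA genes or lists by more than 1.5 times. The array means ended 98 calls of named genes, and leaving out shControl replicate 1 or 2 ended 96 or 97. The samples per group and the signal over background limit what can be called. With these sample numbers, a change of 1 on the log2 scale was recovered for 45% of simulated features in shMyc1 and 46% in shMyc2. Only features past the filter were simulated there, without a background floor or array effect. These shares therefore do not measure the limit set by dim signal. In the simulations, 10.2% to 10.8% of unchanged features had p under 0.05 in the pooled fit and 4.94% to 15.3% without its array block when no dye effect was simulated. The cause of the changes below was not tested, except that fewer samples or arrays lower the precision. Leaving out 1 sample also leaves its group with 1 dye, so a probe's dye effect no longer cancels.

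With the 75th percentile shift, MYC changed by -0.04524 in the pooled comparison and by -0.2554 in shMyc2, H1-2 by -0.02433, and the medians of MYC network partners, the integrated stress and unfolded protein response and replication-dependent histones were -0.163, -0.218 and -0.147. Without a filter on dim probes 1 non-coding gene changed, a fall and none of the 3 of the main fit, 129 features in shMyc1, 683 in shMyc2, 51 between the shRNAs and 91 under both, and the medians of the lncRNA and epithelial lists were -0.00484 and 0.0151. With probes above background in all 6 channels 1 non-coding gene changed and 15 features differed between the shRNAs. The mean of a gene's probes gave MYC network partners a median of -0.00458, and the deposited matrix gave the stress response list -0.0161.

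Pairing the samples by replicate number is the same as the dye term. As a replicate block on the deposited matrix it gave 1256 features, 282 mRNA genes and 0 non-coding genes (5 at an unadjusted p under 0.05) in the pooled comparison, 2509 in shMyc1, 7393 in shMyc2, 42 between the shRNAs and 2125 under both, with -0.0161 for the stress response list. The dye term on the scanner values gave 1003, 237 and 0 (5 unadjusted), then 2215, 7257 and 1896 under both. Of 131 named genes followed, 98 were called in the pooled comparison, and the dye term ended 52 of these calls. It called 20 lists in the pooled comparison, 18 in shMyc1 and 20 in shMyc2, against 19, 16 and 17.

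Without the array block 2476 features, 523 mRNA genes and 0 non-coding genes changed (6 unadjusted), and with array means 0, 0 and 0 (5016, 922 and 4 unadjusted). For custom probes these counts were 696 and 0 (1626 unadjusted). Comparing only the 2 groups gave 202 features for shMyc1 and 2465 for shMyc2. Without the shMyc2 array 202 features, 44 mRNA genes and 0 non-coding genes (3 unadjusted) changed, H1-4 had 0.1189, ALAS2 -0.06766 and MYC network partners -0.00977. Without the shMyc1 array 2465 features and 0 non-coding genes (6 unadjusted) changed, with -0.0907 for the stress response and -0.207 for histones. With an estimated correlation 0 lists passed with camera in the pooled comparison, 0 in shMyc1 and 0 in shMyc2, while fry called 20, 5 and 20. Trend and robust settings of limma gave 1 non-coding gene, 1375 features in shMyc1, 92 between the shRNAs and 1197 under both. At an adjusted p under 0.01 the counts were 124 pooled, 5 in shMyc1, 197 in shMyc2, 5 between the shRNAs and 3 under both.

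Leaving out 1 sample, with the lone sample assumed to vary like the others, gave 25 (without shControl replicate 2) to 11831 (without shMyc1 replicate 2) pooled features, 2 to 2396 mRNA genes and 0 to 11 non-coding genes. Custom probes numbered 10 (without shControl replicate 2) to 3319 (without shMyc1 replicate 2). The pooled count was 45 without shControl replicate 1, 11302 without shMyc1 replicate 1 and 8704 without shMyc2 replicate 2. It gave 0 to 202 features in shMyc1, 191 (without shMyc2 replicate 2) to 3451 in shMyc2, 6 to 51 between the shRNAs and 0 to 182 under both. MYC ranged from 0.116 to 0.4256 pooled, 0.07525 to 0.8089 in shMyc1 and -0.07878 to 0.3272 in shMyc2. Its level was higher in green than in red on each array, so these ranges include a dye difference. Called lists numbered 18 to 21 pooled, 16 to 19 in shMyc1 and 16 to 20 in shMyc2. Medians ranged from 0.0286 to 0.122 for MYC network partners, -0.165 to 0.0666 for the stress response, -0.28 to 0.334 for histones, 0.0805 to 0.353 for lncRNAs and -0.367 to -0.0947 for the epithelial list. Genes ranged from -0.0522 to 0.5722 for H1-2, -0.5071 to 0.06839 for H1-4, -0.01932 to 0.1476 for ALAS2, -0.07089 to 0.3818 for CSF3R and -0.7137 to 0.09561 for H2BC21.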

Other observations

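The tests of saturation, scaling, exchanged labels and the probe as explanations for MYC, and the test of dim probes in the form given here, were chosen only after the values were seen. The test of immediate-early genes was fixed before its result was seen, on a pattern picked from these data.

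Besides PLAAT2, further genes outside the interferon list were higher in the samples labelled shMyc2 than in those labelled shMyc1, and are named here after their values were seen. CX3CR1, a chemokine receptor gene, was not well above background in shMyc1 and was at least 9.5-fold higher (adjusted p = 0.00506). SERPINF1 was higher by 1.98 (adjusted p = 0.0378) and DAB2IP by 1.81 (0.0314). The unnamed catalogue probe A_23_P45871, also chosen after its values were seen, had levels of 11.46 and 13.22 in the shMyc2 channels, against 2.80 and 3.10 in shControl and 2.56 and 3.01 in shMyc1, where it was not well above background, and was at least 163-fold higher than in shMyc1 (adjusted p = 0.00506). Its target is not given in the sources used here. KCNQ1OT1, a non-coding RNA of an imprinted region, rose by 1.56 in shMyc2 (SE 0.40, adjusted p = 0.0453) while 1 of 19 non-coding genes passed there (5 with the dye term).

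MYC mRNA was not lower in the samples labelled Myc low, although genes known to be activated by MYC were as a list with the preset correlation (camera adjusted p = 9.03e-09, but 0.35 with an estimated one). The MYC spot was flagged as saturated in 0 of 6 channels, which argues against a ceiling. Under 3 other scalings the lowest pooled change of MYC was -0.05, with a lower 95% limit of -0.65 in the pooled fit, which was too liberal in simulations, -0.684 without the array block and -0.751 with array means as the samples. This argues against a choice among these scalings that hid a fall of 1 log2 unit in the signal of this probe, and smaller falls stay open. Each of these scalings brings the arrays to a common level or distribution, so a change in total RNA cannot be seen. The MYC-activated list had a median of -0.795 and an upper quartile of -0.445, where an exchange of the Myc-high and Myc-low labels would give a rise. Only 1 MYC probe with a named target is on the array, so a probe that does not follow the knocked-down transcript may be an explanation, as may a recovery of MYC mRNA by day 8, which was not tested.

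JUN, like BTG2, was higher in the samples labelled Myc low. It was not well above background in shControl, was so in 3 of 4 Myc-low channels, and was at least 2.01-fold higher (adjusted p = 0.0256, 0.0516 with the dye term). The hypothesis was that immediate-early genes may rise together. Of 30 such genes other than these, listed before the test, 19 were measured, 16 were higher, 2 rose past the threshold (JUND by 1.02, adjusted p = 0.012, and ZFP36 by 1.13, adjusted p = 0.011) and 0 fell. Their median was 0.449 and camera gave p = 0.00862, but p = 0.15 with an estimated correlation. The values go with the hypothesis only under the preset correlation.

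HBB, CKM, NPPA and TF, genes of other tissues, were among the largest fitted rises, and 0 of the 2 shControl channels had them well above background. Their rank is uncertain, since only bounds are known. A general rise of dim probes may be an explanation. In both channels of shMyc1 and neither of shControl, 259 probes were well above background, and 494 the reverse, a ratio of 0.524. For shMyc2 these were 510 and 442, a ratio of 1.15. With 1 array per group the brightness of each array also moves these numbers, so the explanation remains open.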
